A study of Eurytemora affinis with 4 samples.

How the data were processed

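Poly(A) RNA from whole adult *Eurytemora affinis*, a calanoid copepod of estuaries and coastal waters, was sequenced from 4 libraries, 2 of female pools and 2 of male pools. Per the labels' protocols, the animals were kept at 13 °C, 15 PSU and 15 h of light to 9 h of dark, the sexes were separated 2 days before collection, and the animals were starved with 6.0 µm beads at 120 µL per L for the last 24 h. The libraries kept the strand of the RNA, per the labels' protocols. The labels do not say whether the pools came from separate cultures, so the p-values may measure only technical spread.

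The submitters' processing notes name TopHat, Cufflinks, edgeR and Cuffdiff with no version, and the genome build is not given in the sources used here. The 8 deposited tables hold the authors' own comparisons of males with females, at the level of transcribed loci and of isoforms. The Cuffdiff tables hold 1 pooled FPKM value (fragments scaled by transcript length and sequencing depth) per sex, per the file headers, with the authors' log2 fold change, p-value and adjusted p-value. The edgeR tables hold the authors' log2 fold change of males over females, the average log2 CPM (counts scaled to a common library total) over the libraries, the p-value and its adjusted value, per the file headers. The remaining tables list the features that the authors deposited as shared by 3 methods, Cuffdiff, edgeR in a gene map mode and edgeR in a Trinity mode. No value per library was analysed here, so no test across libraries was run, no spread between replicates can be given, and the depth of each library is unknown apart from an estimate in the closing section.

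The tables were compared before use. All 6733 loci and all 5867 isoforms of the tables named for the gene map mode stand with identical values in the tables named for the Trinity mode, as their features past an adjusted p of 0.05. The Trinity mode fold changes of the shared set equal those tables for 0 of its 1343 loci, whereas its gene map fold changes equal them for all 1343. The tables named for the Trinity mode were therefore read as the full gene map comparison, with 37449 loci and 47585 isoforms, and Trinity mode values were taken only from the shared set. In the shared set of loci, 3 Cuffdiff fold changes hold a spreadsheet error where the Cuffdiff table has minus infinity, and they were read as such. Some assembled-transcript IDs in the Cuffdiff isoform table have a sequence number replaced by the word female or male, and these were respelled before matching. Of the 37449 loci, 33763 were matched to the Cuffdiff table by ID. Positions are given from 1, whereas the deposited starts count from 0.

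The main count was fixed before the data were examined as the features past an adjusted p of 0.05 in the authors' edgeR gene map comparison, split by the sign of the fold change, with Cuffdiff and the shared set beside it. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. A locus listed at 0 is one with an FPKM of 0 in one sex and of at least 1 in the other. The rule for naming loci, also fixed before, took the 2 male-biased and the 2 female-biased loci with the largest absolute log2 fold change among those called in the same direction by all 3 methods, with an FPKM of at least 1 in one sex. The scaffold regions named were chosen after their values were seen. The files pair no gene names with the loci, so the 16 gene lists fixed beforehand were not tested.

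The level of a locus in each sex was derived from the authors' average log2 CPM and log2 fold change, and is called the implied level. It includes the small prior count that such a fit adds to each library. Pairs of neighbouring loci were counted over the 33704 placed loci, and the calls were permuted 1000 times within 10 strata of abundance, one-sided. On simulated calls scattered over those loci the ratio of observed to permuted pairs was 0.965, and with 100 planted runs it was 1.68. With an uncalled locus required between the pair, the ratios on simulated calls were 1.02 for scattered calls and 1.73 for 200 planted runs in which called and uncalled loci alternate. In that count, 100 planted runs of plain neighbours gave 0.819, so that it did not detect unbroken runs there. All these simulations used pairs up to 10000 bases apart, 100 permutations and no strata. Those without the required uncalled locus also counted overlapping pairs. On the data, the count with an uncalled locus between reached 50000 bases, so that the simulations do not match it in full. Loci that overlap another locus share positions, and the tables do not tell how reads were divided between them; 42.4% of the sex-biased loci do so, and their values are uncertain. Alternatives were the Cuffdiff comparison, other thresholds on the adjusted p, the fold change and the abundance, recomputed Benjamini-Hochberg values and centred fold changes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.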

Results

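Gene expression was compared between adult males and adult females of the copepod *Eurytemora affinis*, with 2 libraries of pooled whole animals per sex. The question was which transcribed loci and isoforms differ in expression between the sexes. Values are those of the authors' deposited tables, with a positive log2 fold change for higher expression in males.

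Of 37449 transcribed loci in the authors' deposited table of the edgeR gene map comparison, 6733 were sex-biased at an adjusted p under 0.05, which is 18.0%. Female-biased loci were more frequent, with 3588 against 3145 male-biased loci. The male-biased share was 46.7% (95% Clopper-Pearson interval 45.5% to 47.9%), but 50.6% of the 3106 loci at an adjusted p under 0.001. The male-biased loci differed by more, with a median log2 fold change of 2.09 against -1.74 for the female-biased loci in the authors' deposited table. Among loci with an absolute log2 fold change of at least 2, male-biased loci outnumbered female-biased ones by 1643 to 1433. At 6 or more the authors' deposited table held 845 male-biased and 109 female-biased loci, and at 10 or more 217 and 1. Fold changes of this size depend on the prior count of the fit wherever one sex has almost no reads, and are no bounds.

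**Figure D1:**
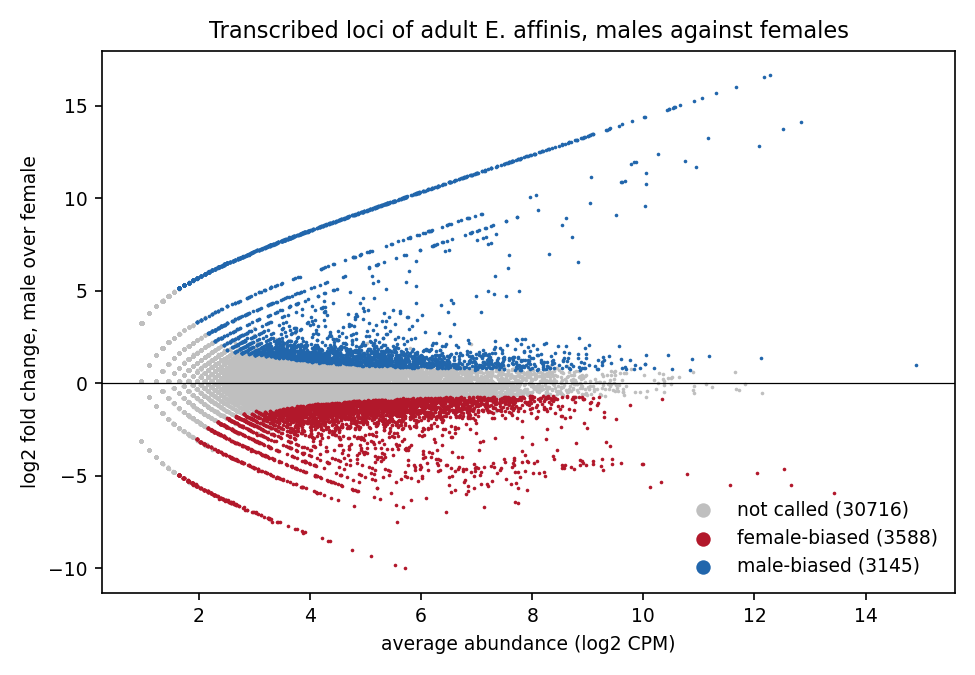
Each point is a transcribed locus, with its average abundance in log2 CPM on the horizontal axis and its log2 fold change, male over female, on the vertical axis, from the authors' deposited table. The 3145 male-biased loci reach a log2 fold change of 16.63, and the 3588 female-biased loci reach -10.01.

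**Figure D2:**
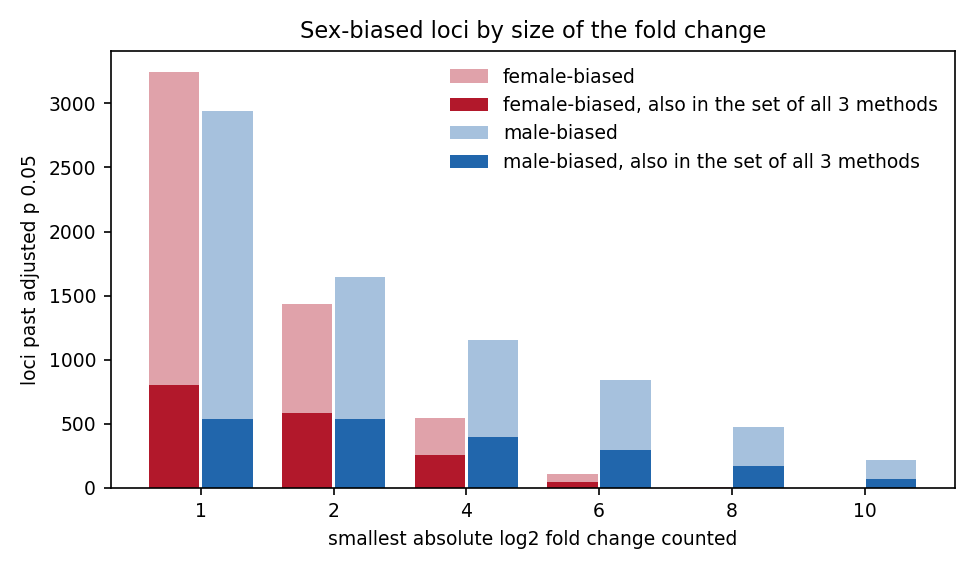
Bars give the number of sex-biased loci with at least the absolute log2 fold change on the horizontal axis, and the dark part gives those also in the authors' deposited set of all 3 methods. At 1 or more there were 3248 female-biased and 2943 male-biased loci, and at 4 or more 548 and 1155.

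The sex-biased loci held a large part of the RNA of each sex. By implied level, male-biased loci made up 42.7% of the male total and 9.75% of the female total. Female-biased loci made up 35.5% of the female total and 8.33% of the male total. The 20 most abundant male-biased loci held 13.5% of the male total and 2.44% of the female total. One of them, on a contig not placed on a scaffold, accounted for most of that female share: the other 19 held 9.90% of the male total and 0.372% of the female total. Cuffdiff left the unplaced locus untested for too few fragments, so that its level is uncertain. The 20 most abundant female-biased loci held 8.44% of the female total and 0.375% of the male total. These totals come from the authors' deposited table and have no error, since no value per library was analysed here.

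The largest differences were on the male side. In the authors' deposited table, GENE_0016277 on Scaffold217, bases 583085 to 586684, was listed at 0 FPKM in females and at 1197 FPKM in males, and all 3 methods called it male-biased (edgeR gene map adjusted p = 2.85e-96). It overlaps another locus listed by Cuffdiff, so that its FPKM values are uncertain. GENE_0027325 on Scaffold22, bases 1426065 to 1429350, had 0.0936 FPKM in females and 216 FPKM in males in the authors' deposited table. Its log2 fold change there was 13.68 by the edgeR gene map comparison, 12.74 by the edgeR Trinity mode and 11.17 by Cuffdiff. The 13.68 implies the female level that the closing section reads as no female reads, so that its size rests on the prior count.

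On the female side, GENE_0145846 on Scaffold372, bases 133141 to 136543, had 15.2 FPKM in females and 0.0319 FPKM in males in the authors' deposited table. Its log2 fold change there was -8.07 by the edgeR gene map comparison (adjusted p = 6.96e-14) and -8.90 by Cuffdiff (adjusted p = 0.0358). The -8.07 implies a male level close to that of no male reads, so that its size rests largely on the prior count. GENE_0150140 on Scaffold419, bases 21799 to 35752, had the largest female bias in the authors' deposited table, -10.01 by the edgeR gene map comparison. Cuffdiff gave it 114 FPKM in females and 47.5 FPKM in males, a log2 fold change of -1.26 in the authors' deposited table. The -10.01 implies a male level close to that of no male reads, so that the tools conflict on its male expression. This locus overlaps 2 other tested loci, so that its reads are uncertain.

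The most abundant sex-biased loci differed in the strength of their calls. On Scaffold37, the female-biased loci at bases 1781387 to 1787485 and 1763269 to 1769379 had log2 fold changes of -5.94 and -5.50 in the authors' deposited table, with edgeR adjusted p values of 9.59e-05 and 0.000231. On Scaffold145, the loci at bases 80228 to 86797 and 91763 to 94383 had -4.67 and -4.86 in the authors' deposited table, with edgeR adjusted p values of 0.00756 and 0.00666. Among loci with an average log2 CPM of at least 10, the authors' deposited table held 36 male-biased loci with a median edgeR adjusted p of 2.52e-94 and 9 female-biased loci with a median of 0.000231. Across the 115 female-biased loci with an average log2 CPM of at least 6 and a log2 fold change of -4 or lower, the size of the fold change did not rise with abundance (Spearman's rho -0.097, across loci, which are not independent replicates). Across the 258 male-biased loci of 4 or higher rho was 0.701, and 0.571 across the 90 of them above 0 female reads. With no or few female reads the fold rises with abundance, so that this is no fair contrast. Cuffdiff left 15 of the 36 male-biased and 5 of the 9 female-biased loci of at least 10 log2 CPM untested for too many fragments.

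Strongly male-biased loci lay in runs on the scaffolds, and the tables do not tell whether neighbouring loci are parts of one gene. With a log2 fold change of at least 8 and gaps of at most 50000 bases, 19 runs of 4 or more loci held 102 of the 449 placed loci of that size in the authors' deposited table. The run on Scaffold154, bases 201122 to 270707, held 7 such loci at 6 positions among 9 tested loci. Their log2 fold changes ranged from 10.84 to 16.53 and their average log2 CPM from 9.08 to 12.51 in the authors' deposited table. On Scaffold230, bases 66457 to 144468, 10 loci of that size at 8 positions stood among 17 tested loci. On Scaffold230 as a whole, 21 of 36 tested loci were male-biased in the authors' deposited table, against 8.64% of all placed loci. On Scaffold318, bases 286812 to 350603, 12 loci of that size shared 5 start positions. At the looser cut of -4 or lower, 8 female-biased runs of 4 or more loci held 38 of 479 placed loci. The cuts differ, so that the runs of the 2 sexes are no matched comparison. On Scaffold174, bases 709554 to 769773, all 7 tested loci, at 5 positions, were female-biased with log2 fold changes from -6.04 to -4.27 in the authors' deposited table.

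**Figure D3:**
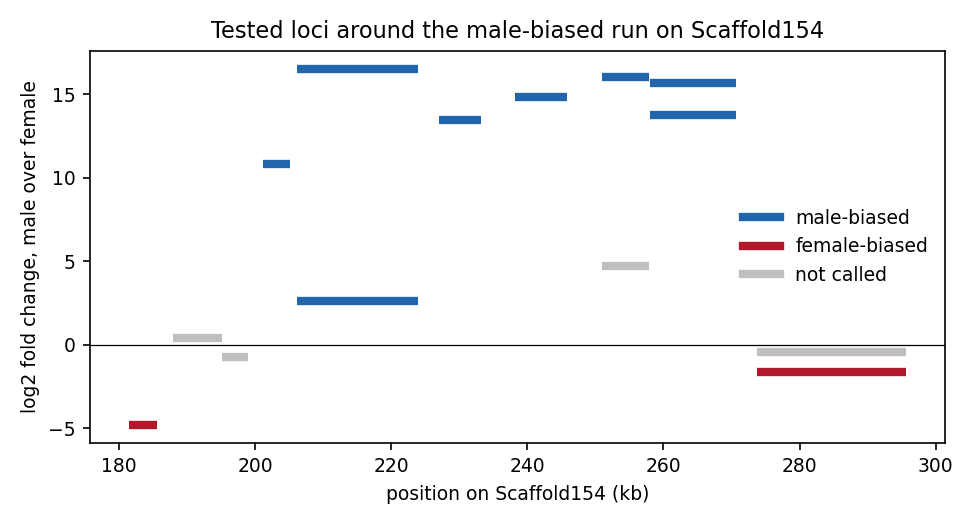
Each bar is a tested locus around the run on Scaffold154, drawn from its start to its end in kb, at its log2 fold change, male over female, in the authors' deposited table. The 7 loci of the run lie between 10.84 and 16.53, and a female-biased locus before the run lies at -4.81.

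Over all male-biased loci, pairs 1 to 10000 bases apart were 2.27 times as frequent as with permuted calls (one-sided permutation p = 0.001, the smallest the permutations can give). For female-biased loci the ratio was 2.31 (one-sided permutation p = 0.001). Beyond 66669 bases, the length of the longest locus, and up to 200000 bases, the ratios were 0.987 and 0.997, within the range of permuted calls. For male-biased loci with a log2 fold change of at least 8 the ratio at that distance was 1.49, above the range of permuted calls, 0.695 to 1.31 (one-sided permutation p = 0.001).

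Cuffdiff called 7335 loci in the authors' deposited table, 2965 male-biased and 4370 female-biased, out of 41996 tested. The male-biased share was 40.4% (95% Clopper-Pearson interval 39.3% to 41.6%). Among the 25515 loci tested by both tools, 1238 were male-biased and 1923 female-biased in both of the authors' deposited tables, where independent lists of those sizes would share 199 and 382. The lists are not independent, since both tools were run on the same animals' libraries, so an excess over these numbers is no measure of reliability. Another 5 loci were called in opposite directions. Across the 30543 loci with a finite fold change in both, the sign was the same for 81.4% (95% Clopper-Pearson interval 81.0% to 81.9%). Across these loci, which are not independent replicates, Pearson's r was 0.632 and Spearman's rho 0.744.

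The authors' deposited set of all 3 methods held 1343 loci, of which 1339 had the same direction throughout. Of these, 536 were male-biased and 803 female-biased, a male-biased share of 40.03% (95% Clopper-Pearson interval 37.4% to 42.7%). The overlap of 3 independent lists could not be computed, since the Trinity mode calls outside the set were not analysed here. In this set the median log2 fold change of the edgeR gene map comparison was 6.41 for male-biased and -2.83 for female-biased loci.

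Of 47585 isoforms in the authors' deposited table of the edgeR gene map comparison, 5867 were sex-biased, 2683 male-biased and 3184 female-biased. The male-biased share was 45.7% (95% Clopper-Pearson interval 44.4% to 47.0%), but 52.9% of the 2520 isoforms at an adjusted p under 0.001. The authors' deposited set of all 3 methods held 710 isoforms, and 708 had the same direction, 370 male-biased and 338 female-biased. That share of 52.3% had a 95% Clopper-Pearson interval of 48.5% to 56.0% and did not separate it from equal numbers of both. Of 3325 loci with at least 2 tested isoforms, 44 (1.32%) had both a male-biased and a female-biased isoform in the authors' deposited table. Only 12.3% of the tested isoforms were called, so that this low share is no measure of agreement between the isoforms of a locus. Of these 44 loci, 24 were not called as loci, 14 were female-biased and 6 were male-biased.

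Expression was listed at 0 in one sex more often for females. In the authors' deposited Cuffdiff table, 1534 loci were at 0 in females with at least 1 FPKM in males, and 898 were at 0 in males with at least 1 FPKM in females. Cuffdiff called 562 and 325 of them in the authors' deposited table. Their median lengths were 246.5 and 247.5 bases, against 3819 bases for all loci, and an FPKM of 0 can be a failed estimate.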

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

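The tests of the ceiling on the fold change, of fold size against abundance, of overlapping loci, of split genes with uncalled loci redrawn, of the strong loci, of female RNA in the male pools, of the fragment limit and of small female FPKM values were chosen after their results, or the values that set them, had been seen.

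Calls outside the main comparison stood in the Cuffdiff table. Among its 16481 tested loci that the edgeR table lacks, Cuffdiff called 1744 in the authors' deposited table, 913 male-biased and 831 female-biased. That is a smaller share than the 17.5% called over all loci that Cuffdiff tested. The median length of the 1744 was 474 bases, against 5504 bases for called loci in both tables.

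Fold changes were larger on the male side. Among female-biased loci with an average log2 CPM of at least 6 and a log2 fold change of -4 or lower, the fold size did not rise with abundance (Spearman's rho -0.097 across 115 loci). Of these loci, 95.7% lay between -6 and -4, against 3.49% of the 258 male-biased loci of 4 or higher between 4 and 6. The cut at -4 is itself an edge of that band. It also restricts the range of the fold sizes, which may pull rho toward 0. The same relation on the male side is no fair contrast, since 168 loci there lay at the level of 0 female reads, where the fold is set by the prior count. With those left out, rho was 0.571 across 90 male-biased loci, with a median log2 fold change of 8.33. Loci with only 1 or 2 female reads stay among the 90. At such a fixed female level the fold rises with abundance, so that this contrast does not decide either. A different ceiling in each sex is argued against, since the levels that stand for 0 reads differ by 0.089 log2 units. Female RNA in the male pools and low expression in the males themselves cannot be told apart here: 0.763% of 131 abundant female-biased loci (1 locus) had an upper 95% limit on the male share below 1 in 64, but that limit was set from these fold changes and only 8 of the 131 lay beyond it. A single share for all loci would also have to account for 109 female-biased loci of 6 log2 units or more. The largest of these, at -10.01, overlaps 2 other tested loci, so that its reads are uncertain, and Cuffdiff gave it -1.26. Such a share would likewise have to account for 7 loci of average log2 CPM of at least 4 with no male reads. At 3.94%, the median male share of the 131 loci, at least 3.9 reads would be expected at each of the 7. The cut at -4 bounds that median, so that it is no estimate of a share common to all loci. The lowest upper limit on the male share among the 131 was 1.07%, at which fewer reads would be expected. The count of loci with no male reads was 0 at 6 log2 CPM or more, and none of this decides.

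Male-biased loci lay next to each other. Overlap is argued against as the whole cause, since pairs 1 to 10000 bases apart were still 2.27 times as frequent as with permuted calls. Whether one gene split into several loci accounts for the rest cannot be told apart from clustering. With an uncalled locus between pairs up to 50000 bases apart, the ratio was 1.06, and 1.05 with the uncalled loci redrawn. Both lay within the range of permuted calls. Simulated runs of neighbouring loci gave 0.819 in a similar count, which reached only 10000 bases and used no strata, so that a ratio near 1 does not decide. For female-biased loci the same ratios were 1.27 and 1.26, above the range, whose upper limit was 1.07. For loci with a log2 fold change of at least 8 the ratio was 4.01 with the uncalled loci redrawn, above the range of permuted calls. That argues against splitting into unbroken neighbours as the whole cause there, although an uncalled locus can lie inside an intron. For pairs farther apart than the longest locus the ratio was 1.49, also above the range. It does not decide on splitting, since a gene split into several loci can be longer than the longest locus. The permuted calls also treat overlapping loci as separate. Pairs of overlapping strong loci were 18.1 times as frequent as with permuted calls, so that these ranges may be too narrow. Clustering of genes with male-biased expression and reads shared by near-identical copies were not tested and stay open.

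Cuffdiff did not call 147 of the 217 loci with a log2 fold change of at least 10 male-biased. It called 70 of these 217 loci male-biased, a smaller part than the 1234 of 2943 loci at 1 or more. The set of all 3 methods held 69 of the 217 and 538 of the 2943, a larger part of the strongest loci, but 170 of the 478 loci at 8 or more. Cuffdiff's limit on fragments is argued against as the main cause, since it covered 12.9% of the 147 loci. A female FPKM just above 0 may be part of it, tested on the wider set of loci with a log2 fold change of at least 8 that Cuffdiff tested: it called 80.4% of 56 loci at exactly 0 but 18.2% of 203 loci above 0 and up to 0.05, a difference of 62.1 percentage points (Fisher's exact test, two-sided p = 9.32e-18, across loci). Above 0.05 it called 77.4% of 115 loci, but their median male FPKM was 76.7, against 8.17 in the middle class, so that abundance differs too. No biological explanation was tested.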

How the results depend on the processing

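The alternatives without overlapping loci and without short loci, and those of the shares under a stricter adjusted p and, for isoforms, a fold change floor, were chosen after seeing the data. Of 46 alternative values, 20 stayed within the limits set for their kind: counts within 1.5 times the reported count, shares within the 95% interval, and named loci in the same direction and past an adjusted p of 0.05. These limits do not bound the fold change of a named locus, which was -10.01 by the edgeR gene map comparison and -1.26 by Cuffdiff for GENE_0150140 in the authors' deposited table. Sex-biased loci numbered 3106 at an adjusted p under 0.001, 3076 with an absolute log2 fold change of at least 2 and 3236 without overlapping loci. Isoforms numbered 3812 at 0.01, 2520 at 0.001 and 3717 with a log2 fold change of at least 2. Fewer features pass a stricter limit by construction. The male-biased share of loci was 53.4% with a log2 fold change of at least 2. At an adjusted p under 0.001 it was 50.6%, close to equal numbers of both. It was 40.4% by Cuffdiff, 45.2% with the abundance floor, 48.1% without overlapping loci, 40.03% in the set of all 3 methods and 44.4% with centred fold changes and a floor of 1. The share of isoforms was 40.4% by Cuffdiff and 52.9% at an adjusted p under 0.001. In the set of all 3 methods it was 52.3%, which was not separated from equal numbers of both. It was 48.4% at 0.01 and 49.1% with a log2 fold change of at least 2. The cause was not tested. The set of all 3 methods held 744 loci at 0.01 and 497 at 0.001, and 429 and 278 isoforms. The sign of the fold change was the same for 87.7% of loci with an FPKM of at least 1 and for 99.8% of those called in both. Loci listed at 0 numbered 1053 and 632 with at least 5 and 10 FPKM in the other sex.

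No paired analysis was possible because no value per library was analysed here. For the same reason, leaving out each library, other normalizations, count filters, other tools, pseudocounts and filters on low values were not run. The gene lists and the Trinity mode count were not run, for want of names and of Trinity mode values outside the shared set. How far depth limits the calls was not tested; the median average log2 CPM was 1.97 for loci not called and 4.39 and 4.63 for male-biased and female-biased loci in the authors' deposited table.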

Other observations

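The test of whole reads was chosen after its result had been seen.

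The implied female level of abundant male-biased loci fell on a few values. Among 242 loci with an average log2 CPM of at least 6 and an implied female level under 2.5 CPM, 168 lay at 0.098 CPM, 29 at 0.473 CPM and 31 at 0.848 CPM, with values derived from the authors' deposited table. A candidate explanation is whole reads in the females, where the lowest level is the prior count alone. Of the levels, 100% lay within 0.1 of a whole number of steps of 0.375 CPM, against 20.7% of simulated continuous levels. The step was set from the groups at 0.098 and 0.473 CPM, whereas none was fitted to the continuous levels. Only the loci above 0.473 CPM therefore test the reading of whole reads. On that reading 1 read over both female libraries is 1 step and a library held about 1.33e+06 counted reads, and the 168 loci had no female read. Among loci with an average log2 CPM of at least 4, 377 of 1798 male-biased loci lay at the level of 0 female reads, against 7 of 2300 female-biased loci at that of 0 male reads. At 6 or more these numbers were 168 of 684 and 0 of 797.

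Contigs not placed on a scaffold carried 13 of the sex-biased loci of the main comparison among 59 tested. They included the most abundant of all 37449 tested loci, with an average log2 CPM of 14.91 and a log2 fold change of 0.97 in the authors' deposited table (edgeR adjusted p = 0.00119). Cuffdiff left this locus untested for too few fragments, so that the tools conflict on its abundance, which is uncertain. A further 629 sex-biased loci of the main comparison were not in the Cuffdiff table, 227 male-biased and 402 female-biased.

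Summed FPKM was set by very short loci. The 1784 loci shorter than 200 bases, 2.89% of all, held 94.0% of the female and 93.2% of the male FPKM total in the authors' deposited Cuffdiff table.

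The 44 loci with isoforms called in opposite directions were abundant, with a median average log2 CPM of 7.36 against 4.53 for all loci with at least 2 tested isoforms in the authors' deposited table. A locus enters this group only if at least 2 of its isoforms are called. Called loci are more abundant in general, so that the difference may be built into the selection.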
